A study of Caenorhabditis elegans with 16 samples.

How the data were processed

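Early embryos of 2 Caenorhabditis elegans mutant strains, met-2(n4256) and set-25(n5021), were used for ChIP-seq of H3K9me2 and H3K9me3 with an input for each ChIP. Per the labels' protocols, chromatin came from 2 independent biological replicates, was fixed with 2% formalin and sheared by sonication. Libraries were made with a NEBNext kit without size selection and sequenced in pairs on a HiSeq 2500, per the series' design text. PCR duplicates were part of any such library, and whether they were removed is not given in the sources used here.

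The deposited table holds raw counts per 500 bp window for 8 columns, 1 for each combination of mark, strain and ChIP or input. The unit was read from the values, which are whole numbers with a different total in each column. The aligner, the counting tool, the treatment of reads that map to several places and the genome build are not given in the sources used here. The deposited counts were thus used as they stand, and repeats may hold more or fewer counts than their copy number would give. Each column was assigned to its group by its name. The name of the H3K9me3 ChIP column of met-2 ends in 1, which may or may not mean replicate 1. The other names carry no replicate number, and no name shows whether the counts of both replicates were added. The last of 198088 lines was incomplete and was left out, which left 198087 windows. Windows of X end at 16493500, and the rest of X is not analysed here.

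The planned tests were written before the data were examined, for log2 enrichments with 2 replicates per group: limma per window and per gene, camera over gene lists, and permutation tests. The table turned out to hold counts with 1 column per group. None of these tests was run, since no spread between replicates can be estimated, and a test on reads would compare libraries and not strains. No genome sequence was used here. The gene table at hand (WBcel235) has genes beyond the last window of 4 of the 5 autosomes, so its build differs from that of the windows. No gene-level, gene list, soft-mask or tandem repeat result is therefore given, and positions are those of the windows, counted from 1, on the build of the deposited counts. The gene table served for names, for the order of neighbouring genes and for the share of piRNA genes on each chromosome.

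Counts were scaled to the column's total (CPM). Enrichment was log2 of ChIP plus 0.1 CPM over input plus 0.1 CPM, with each ChIP over its own input. Windows with under 20 counts in any of the 4 inputs, 6947 in all, were left out, which kept 96.5%. The floor, and the use of thresholds of size in place of tests, were chosen after the format of the table was known. A window was called enriched above a log2 ratio of 1, as planned, and different between libraries at an absolute difference of at least 1. Chromosome arms were taken as the outer 25% of the length of each of the 5 autosomes at either end and the middle as the remaining 50%, as planned. X was not divided. Domains are runs of at least 10 adjacent enriched windows, a definition made after the data were examined.

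Regions were named by the part of the planned rule that needs no gene: the 5 longest runs of adjacent windows per direction and strain comparison that differed by at least 1 and were enriched in the higher library. The planned condition of an adjusted p could not be used. For regions, ChIP and input counts were summed and the 95% interval of the log2 ratio came from the exact (Clopper-Pearson) binomial interval of the ChIP share. Counts in missing runs have exact two-sided Poisson intervals, whose upper limit for a count of 0 is 3.69 counts. Since amplified reads are not independent molecules, all these intervals cover counting error only. Intervals of the difference between arms and middle came from 1000 bootstrap draws of 1 Mb blocks and describe variation along the genome within a library. Runs missing from an input were 2 or more adjacent windows with counts below 10% of the column's median where the input of the other strain for the same mark held over 40% of its own. The expectation came from 10 windows on each side, leaving out the window next to the run, and this search was designed after the data were examined.

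At the median window the 95% Poisson interval spanned 8.87% to either side in the deepest library, the H3K9me3 input of met-2, and 30.6% in the H3K9me2 ChIP of set-25, so that single windows of the ChIP libraries with few counts are less reliable than regions. The scripts were tested on simulated data. For each of the 4 ChIP libraries, counts were drawn from the real inputs with 200 of the 191140 windows enriched 4- or 8-fold. These 200 were recovered at 100%, and 0 of the other windows, drawn with no enrichment, lay above the threshold. Each draw was divided by the same input it came from, so input noise and differences in composition were absent, and 0 was nearly fixed in advance. Real libraries vary more than such draws, which therefore say little about scattered single windows.

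Alternatives written before the data were examined were centring each library on its median, quantile normalisation, a filter on mean enrichment above 0, 5 kb windows, a pseudocount of 1 CPM, enrichment thresholds of 0.5 and 2, wider arms of 33.3% of the length at either end, and medians in place of means. Added after seeing the data were no input floor, the input of the other strain, the input of the other mark, no input, and totals without the 5% of windows with the most counts in any column. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.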

Results

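Chromatin immunoprecipitation sequencing (ChIP-seq) of 2 repressive histone marks, H3K9me2 and H3K9me3, was carried out on early Caenorhabditis elegans embryos, before the bean stage, from worms kept at 20 °C. The worms were met-2 or set-25 mutants. MET-2 is a histone methyltransferase that makes mono- and dimethylated H3K9, and SET-25 is the methyltransferase on which H3K9 trimethylation in worm embryos depends. The labels list 16 samples, a ChIP and an input for each mark in each mutant with 2 biological replicates, so 8 groups. The table analysed here holds 1 column of whole-number counts per group over 198087 windows of 500 bp, and does not say whether a column is 1 replicate or a sum. No difference below could therefore be set against replicate error. No test was run, and the intervals given cover counting error only, except for those over blocks of the genome.

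The ChIP libraries held 26568332 counts for H3K9me2 in met-2, 19777605 for H3K9me2 in set-25, 58645635 for H3K9me3 in met-2 and 19732750 for the H3K9me3 library labelled set-25. The matching inputs held 34007808, 44992666, 114221896 and 49395989 counts. The median window held between 41 counts, in the H3K9me2 ChIP of set-25, and 488 counts, in the H3K9me3 input of met-2. Enrichment was the log2 ratio of ChIP to its own input after scaling to CPM, over the 191140 windows with at least 20 counts in each of the 4 inputs. The H3K9me3 ChIP labelled set-25 had no count in 16520 of these windows, against at most 53 in any other ChIP library, so its lowest values rest on the pseudocount.

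The mutations were looked for first, as runs of windows missing from an input. Both mutated genes lie on chromosome III, and 2 runs on III were missing from inputs. From 8376501 to 8377500, both met-2 inputs held 0 counts, where their flanks predicted 439 (H3K9me2) and 1225 (H3K9me3) (a count of 0 has an exact 95% upper limit of 3.69 counts). The H3K9me2 ChIP of met-2 also held 0, and the H3K9me3 ChIP of met-2 held 6 of 449 expected. This run was taken as the met-2 deletion. From 13287501 to 13289000, the H3K9me2 input of set-25 held 4 counts of 600 expected, its ChIP 6 of 341, and the H3K9me3 input labelled set-25 held 2 of 806. This run was taken as the set-25 deletion.

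Both H3K9me2 libraries of each strain and both H3K9me3 libraries of met-2 carried the runs as labelled. The H3K9me3 libraries labelled set-25 did not. Their input lacked the met-2 run as well, with 2 counts of 608 expected, whereas the H3K9me2 input of set-25 held 513 of 572. Their ChIP held 1431 counts in the set-25 run, 1.39 times the expectation (95% counting interval 1.32 to 1.46), and in the met-2 run 15 counts of 139.5 expected, although 6.31% of equally long stretches were as low in that library. Read by these 2 runs, the H3K9me3 input labelled set-25 carried both deletions, a pattern that neither strain label gives. The input and ChIP labelled set-25 for H3K9me3 therefore differed from each other and from the H3K9me2 libraries of set-25 at the mutated genes. Every direction below that involves H3K9me3 in set-25 rests on this library, called the library labelled set-25 throughout.

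**Figure D1:**
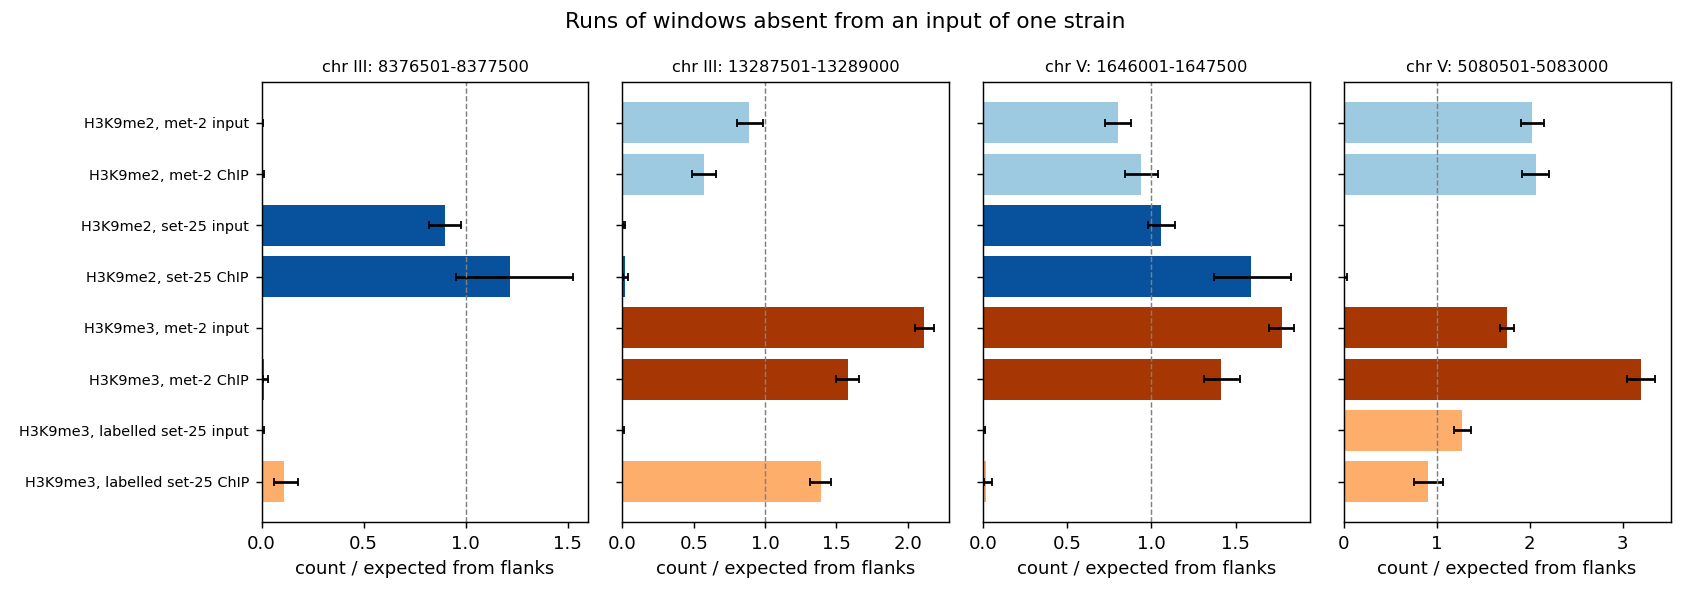
Count in each of 4 runs of windows divided by the count expected from the flanking windows (x axis), for the 8 libraries (y axis). Bars give the ratio, whiskers the 95% Poisson interval of the count, and the dashed line marks a ratio of 1. The run from 13287501 on III is absent from both inputs labelled set-25. It stands at 1.39 in the H3K9me3 ChIP labelled set-25, over flanks that were themselves raised in that library.

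The first comparison asked where H3K9me2 was enriched in each mutant. The labels hold no wild-type sample, so the values do not show what was kept or lost. In set-25 embryos, windows enriched for H3K9me2 were concentrated on the arms of the autosomes. More than 2-fold enrichment was found in 19606 windows (10.3%), and 93.5% of the autosomal ones lay on the arms, taken as the outer 25% of each chromosome at either end, which held 49.5% of the windows. The densest part was the left arm of III, where 47.3% of windows were enriched. The right arm of V (31.2%), the left arms of I (28.4%), II (28.1%) and IV (21.5%) came next, while the middle parts of the autosomes had 0.91% to 2.82% and the measured part of X 3.17%. In met-2 embryos, 2563 windows (1.34%) passed the same threshold, 47.3% of the autosomal ones on the arms. These shares depended on the threshold, the scaling and the input. At a log2 threshold of 0.5 they were 14.2% in set-25 and 11.8% in met-2, and at 2 they were 4.81% and 0.00366%. With each library centred on its median they were 23.8% in set-25 and 1.37% in met-2, and with totals without the most covered windows 17.4% and 1.94%. With the input of the H3K9me3 experiment they were 9.93% in set-25 and 9.30% in met-2, and with the input of the other strain 11.1% and 0.284%.

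The enriched windows of set-25 joined into 332 domains of at least 5 kb, 2.68 Mb in all, with 310 on the arms, 4 in the middle and 18 on X. The left arm of III held 89 of them, the right arm of V 74 and the left arm of II 47. In met-2, 10 such domains were found. Domain numbers, here and for H3K9me3 below, were not recomputed with another threshold, scaling or input, on which the shares of enriched windows depended. Over the 332 domains the median enrichment was 2.73 in set-25 (quartiles 2.21 and 3.36) and 0.17 in met-2 (-0.02 and 0.36), and 7 of them exceeded 1 in met-2.

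The longest run in which H3K9me2 was enriched in set-25 and at least 2-fold above met-2 spanned 33.5 kb on III, from 2913001 to 2946500. Its log2 enrichment was 3.31 in set-25 (3.29 to 3.34) and 0.22 in met-2 (0.18 to 0.27), an 8.52-fold difference. The next was a 28.5 kb run on V from 19011501 to 19040000, at 3.79 against 0.28, which is 11.4-fold. The other runs named by the same rule lay on the left arm of III, from 1669501 to 1693500 (8.88-fold), from 1963001 to 1986000 (8.25-fold) and from 2194001 to 2215500, where H3K9me2 reached 4.22 in set-25 against 0.04 in met-2, an 18.1-fold difference. Relative to each library's median the log2 differences of these 5 runs were larger, 4.37 to 5.50, against 3.04 to 4.17 as scaled to totals.

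Runs with higher H3K9me2 in met-2 were shorter. The 5 longest measured 3.5 to 8 kb and all lay in middle parts: on V from 8477001 to 8485000, where enrichment was 1.42 in met-2 (1.34 to 1.504) and -0.37 in set-25, on IV from 5988501 to 5994000 (1.24 against -0.42), on V from 6145001 to 6149500 (1.21 against -0.52), on III from 9339001 to 9342500 (1.48 against -1.26) and on II from 10708001 to 10711500 (1.31 against -0.43). Relative to each library's median, the difference was at least 1 in only 1 of the 5, the run on III (1.42), and 0.33 to 0.47 in the others, and set-25 stood above its own median in all 5, by 0.07 to 0.95. The same 5 runs carried H3K9me3 in met-2 at 2.57 to 3.82.

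Over all windows the direction depended on scaling. H3K9me2 enrichment was at least 2-fold higher in met-2 in 60.2% of windows and lower in 9.81%, while the median window stood at -1.33 in set-25 and -0.01 in met-2, a median difference of 1.27. With each library centred on its own median, 10.05% were higher and 23.5% lower. Quantile normalisation, which favours near-equal shares by giving all libraries the same distribution, gave 18.9% and 18.4%. Totals without the most covered windows gave 30.9% and 16.1%. Relative to the median difference, 89.8% of the autosomal windows that were lower in met-2 lay on the arms. The mean difference between arms and middle, which centring cannot move, was 1.46 in set-25 (95% interval over 1 Mb blocks 1.24 to 1.68) and positive on each autosome, from 1.01 on IV to 1.89 on III. In met-2 it was -0.08 (-0.12 to -0.04). Under the alternatives the met-2 value ran from -0.041 (medians in place of means) to -0.38 (input of the other mark).

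**Figure D2:**
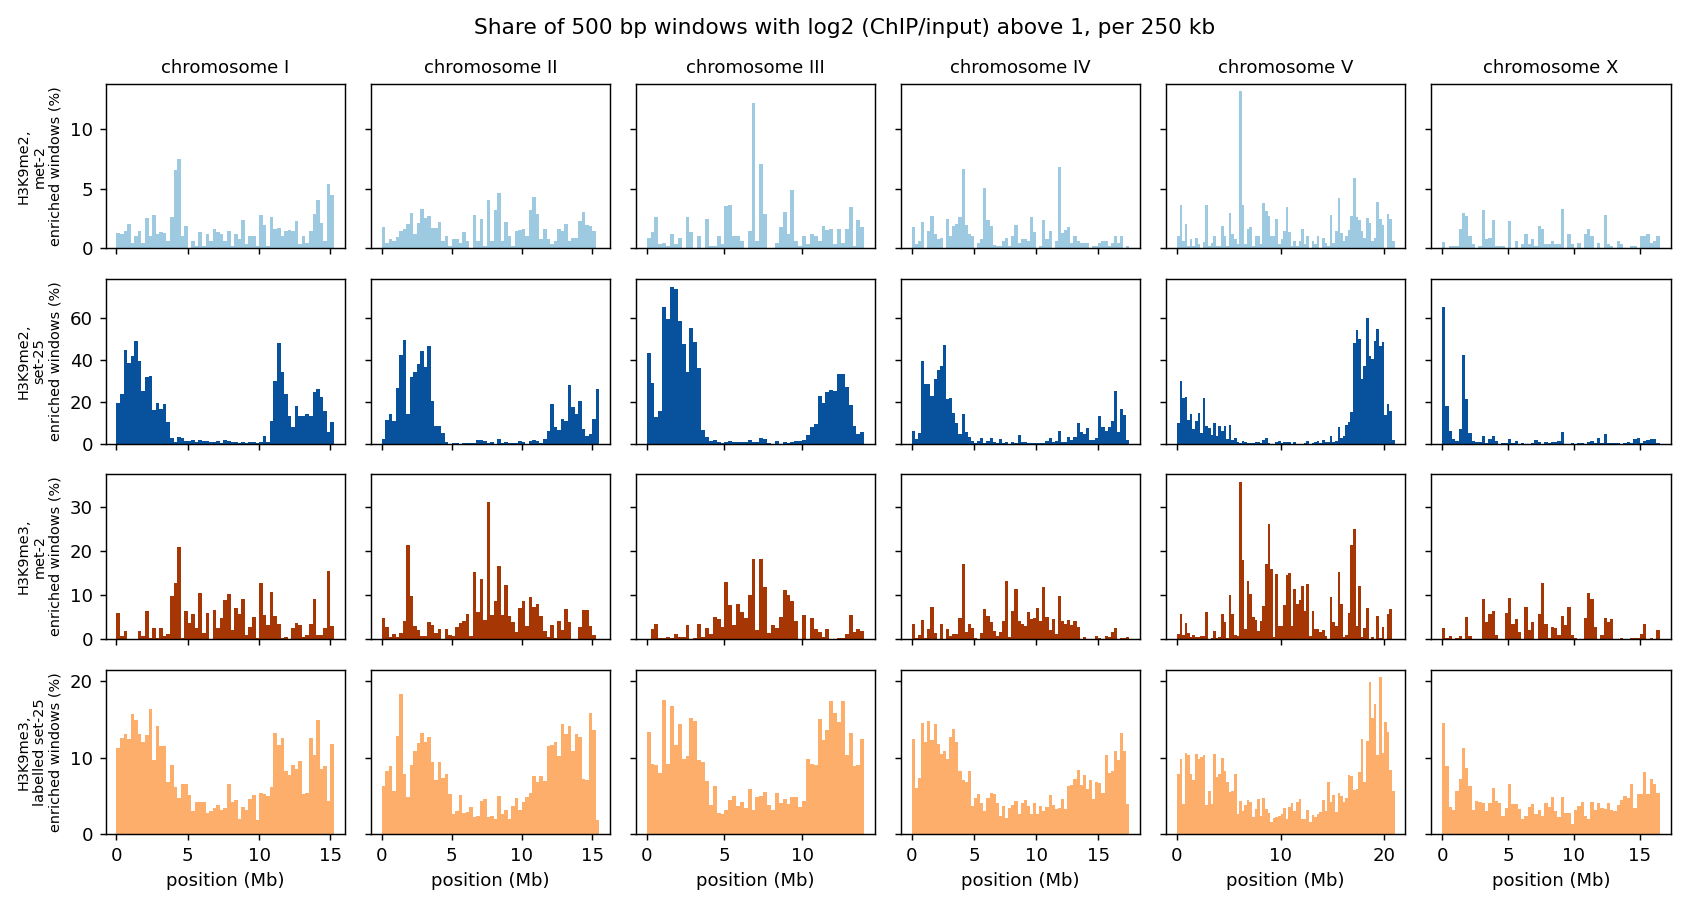
Percent of 500 bp windows with a log2 ratio of ChIP to input above 1 (y axis, a scale of its own in each row) in bins of 250 kb along each chromosome (x axis, Mb), for the 4 ChIP libraries. Enriched windows of H3K9me2 in set-25 are concentrated on the arms, with 47.3% of windows on the left arm of III and 8.29% on the right arm of IV. Those of H3K9me3 in met-2 stand mainly in the middle of the autosomes, with 28.7% of the autosomal ones on the arms. The library labelled set-25 for H3K9me3 did not match its label at the mutated genes.

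The same question was asked for H3K9me3. In met-2 embryos H3K9me3 was found mainly in the middle of the autosomes. Of 7830 enriched windows (4.10%), 28.7% of the autosomal ones lay on the arms. The middle part of V had the highest share, 7.76%, followed by II (6.59%), III (6.14%), I (5.99%) and IV (4.37%), against 0.59% on the right arm of IV and 5.19% on the right arm of V. X had 2.53%. Domains of at least 5 kb numbered 214 and covered 1.78 Mb, with 138 in middle parts, 47 of them on V, 50 on arms and 26 on X.

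In the H3K9me3 library labelled set-25, 13018 windows (6.81%) were enriched, 66.1% of them as single windows, and no domain reached 5 kb. Of the autosomal ones, 70.5% lay on the arms. Whether this library or met-2 had the larger share depended on the threshold. At a log2 threshold of 0.5 the shares were 20.5% and 8.03% in met-2, and at 2 they were 0.266% and 1.46%. With each library centred on its median they were 13.8% and 6.32%, and with the input of the H3K9me2 experiment 17.1% and 10.2%. Over the 214 domains of met-2 the median enrichment was 2.33 in met-2 (quartiles 1.95 and 2.77) and 0.05 in the library labelled set-25 (-0.23 and 0.26), and none of the 214 exceeded 1 in the latter. Enriched windows of the 2 libraries coincided in 434 cases, where 533 would by independent placement and 456 by independent placement within each chromosome part.

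The longest run in which H3K9me3 was enriched in met-2 and at least 2-fold above the library labelled set-25 spanned 27.5 kb on II, from 7726501 to 7754000. Enrichment was 2.68 (2.66 to 2.69) against -0.58 (-0.62 to -0.53), a 9.55-fold difference. It was followed by runs on III from 6747501 to 6773000 (3.12 against 0.11, 8.04-fold), on V from 6138501 to 6162500 (2.81 against -0.39, 9.20-fold), on IV from 11973501 to 11993000 (2.98 against 0.05, 7.66-fold) and on III from 5111501 to 5130500 (2.31 against -0.31, 6.12-fold). All 5 lay in middle parts.

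In the opposite direction the longest run measured 4 kb, on III from 13289001 to 13293000, directly beside the run taken as the set-25 deletion. The library labelled set-25 stood there at 2.08 (2.01 to 2.15) and met-2 at -0.28. The others measured 3.5 to 4 kb, on II from 2997001 to 3001000 (1.54 against -0.34) and from 4516001 to 4519500 (1.58 against -0.67), on I from 14214501 to 14218000 (1.28 against -0.35) and on V from 17782501 to 17786000 (1.46 against -0.04).

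Over all windows, H3K9me3 was at least 2-fold higher in met-2 in 29.7% and lower in 19.6%, with a median difference of 0.08. In windows of 5 kb the shares were 27.3% and 4.33%. Among windows with a mean enrichment above 0 the direction turned, to 14.7% higher and 36.3% lower. That filter used the compared values and favoured windows high in the more variable library, labelled set-25 (SD 1.62 against 0.66 in met-2). This turn therefore decides no direction. With quantile normalisation the shares were 23.6% each. The difference between arms and middle was -0.19 in met-2 (-0.24 to -0.14) and 0.56 in the library labelled set-25 (0.43 to 0.68). The met-2 value became 0.12 when the input of the H3K9me2 experiment replaced its own.

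**Figure D3:**
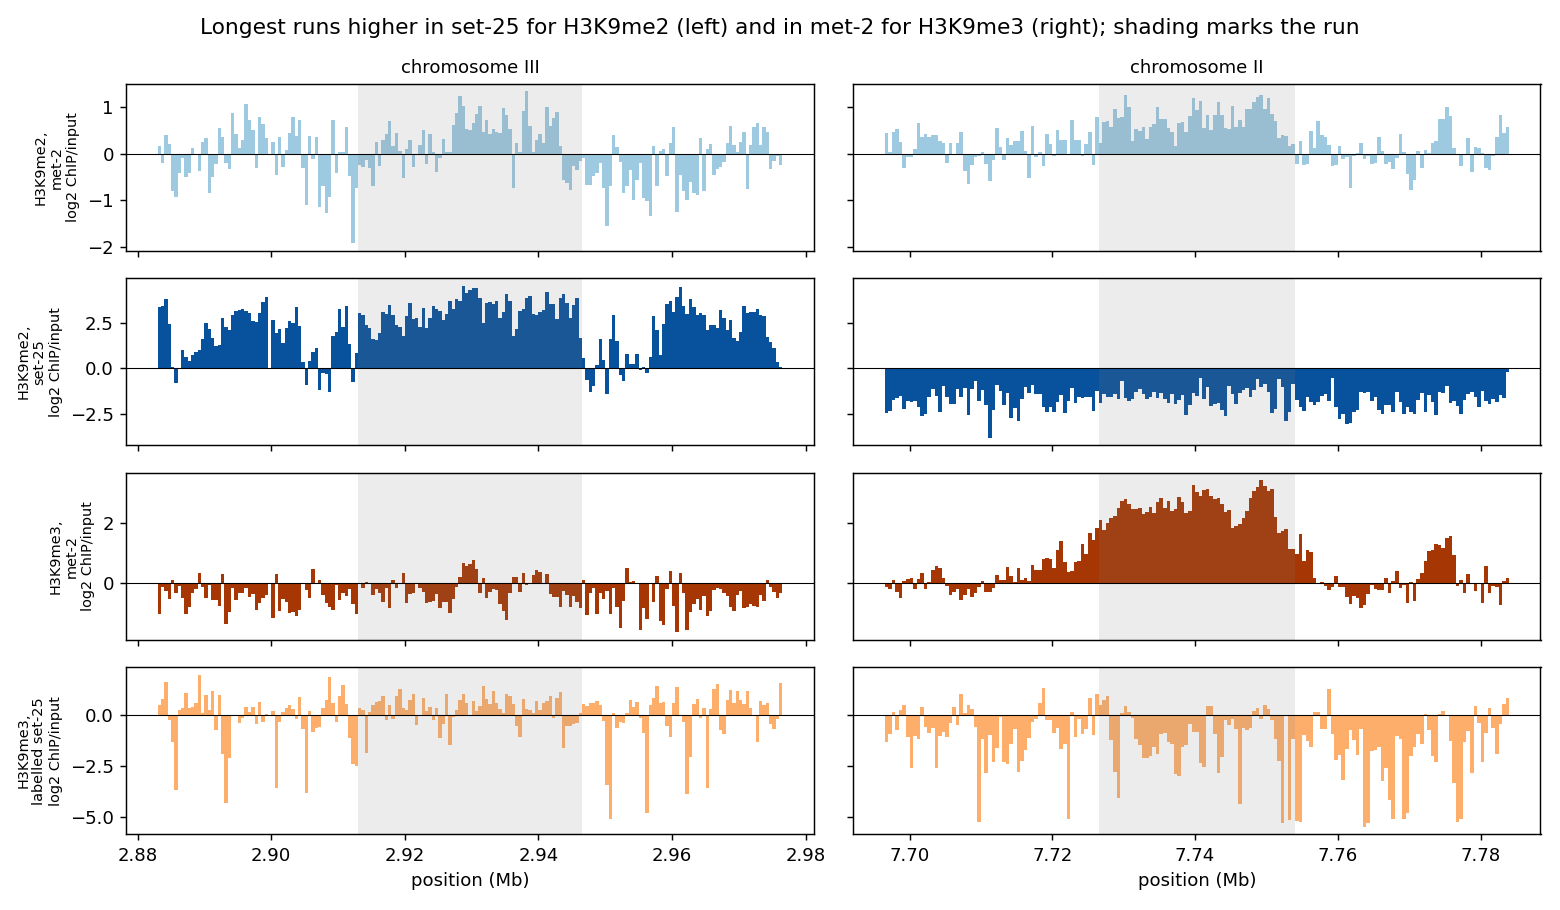
Log2 ratio of ChIP to input per 500 bp window (y axis, a scale of its own in each row) against position (x axis, Mb) for the 4 ChIP libraries. The left column is the 33.5 kb run on III where H3K9me2 stood at 3.31 in set-25 and 0.22 in met-2, and the right column the 27.5 kb run on II where H3K9me3 stood at 2.68 in met-2 and -0.58 in the library labelled set-25. Grey shading marks each run, with 30 kb on either side.

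Within each strain label the marks were compared window by window. The antibodies differ, so the values compare enrichments and not amounts of the marks. Each mark also had its own inputs, whose counts correlated at -0.27 between marks in met-2 and 0.10 under the set-25 label. The composition of the inputs thus cannot be told apart from the marks in these shares. In met-2, most windows above the H3K9me2 threshold were also above it for H3K9me3. Of the 2563 windows enriched for H3K9me2, 1404 (54.8%) were enriched for H3K9me3, against 105 for independent placement and 116 within chromosome parts. Of these 2563 windows 57.9% were single windows, and the overlap was not recomputed with another threshold or input. All 10 H3K9me2 domains of met-2 exceeded 1 for H3K9me3, with a median of 3.24. Over the 214 H3K9me3 domains of met-2, H3K9me2 of met-2 had a median of 0.71 (quartiles 0.58 and 0.85), was above 0 in all 214 and above 1 in 24. H3K9me2 exceeded H3K9me3 at least 2-fold in 13.7% of windows and fell below it in 4.48%, with a median difference of 0.29. With each library centred the shares were 5.32% and 9.16%, and with quantile normalisation 19.9% and 20.6%. With the input of the other mark they were 49.0% and 17.1%, without input 27.4% and 7.42%, and in windows of 5 kb 2.27% and 1.99%. Totals without the most covered windows gave 7.48% and 7.42%.

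The libraries of the 2 marks labelled set-25 differed at the mutated genes, so this comparison is not within 1 genotype. Few H3K9me2 domains of set-25 exceeded 1 for H3K9me3 in the library labelled set-25. Over the 332 domains H3K9me3 had a median of 0.33 (quartiles 0.13 and 0.50), with 288 above 0 and 3 above 1. The median over all kept windows of that library was -0.29. It was 0.09 on the left arm of III and -0.09 on the right arm of V, which held 89 and 74 of the domains. Domain values came from summed counts and these medians from single windows, so -0.29 is not a matched background. Enriched windows of both marks coincided in 2761 cases, against 1335 for independent placement and 1986 within chromosome parts. H3K9me2 exceeded H3K9me3 in 22.9% of windows and fell below it in 39.2%, with a median difference of -0.56, and with each library centred the shares were 38.7% and 15.2%. Quantile normalisation gave 18.8% and 18.6%, and totals without the most covered windows 33.4% and 22.6%.

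The strain difference of H3K9me2 minus that of H3K9me3 was at least 1 on the log2 scale in 45.9% of windows and at most -1 in 21.4%, with a median of 0.81. This difference includes the H3K9me3 library labelled set-25, so it does not compare the marks within 1 genotype either. With each library centred on its median the shares were 16.9% and 41.4%, with quantile normalisation 27.7% each, and with totals without the most covered windows 25.7% and 34.1%. Relative to the median, 61.6% of the autosomal windows on the negative side, where H3K9me2 favoured set-25 more than H3K9me3 did, lay on the arms, against 37.8% of those on the positive side.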

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

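The tests on the set-25 windows were chosen only after the result was seen, and the tests on the other 2 patterns were fixed before their results were computed.

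On chromosome V, 2 runs were missing from libraries labelled set-25 outside the mutated genes. From 1646001 to 1647500 the H3K9me3 input labelled set-25 held 2 counts where 557.85 were expected from the flanks, and its ChIP held 4 of 193.35, while the H3K9me2 input of set-25 held 659 of 622.65. From 5080501 to 5083000 the H3K9me2 input of set-25 held 0 counts where 606 were expected and its ChIP 0 of 117.5, while the H3K9me3 input labelled set-25 held 717 of 561.75. Each run was thus missing for 1 mark and present for the other under the same strain label.

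The H3K9me3 ChIP library labelled set-25 held the windows taken as the set-25 deletion at a ratio of 1.39 (1.32 to 1.46) over raised flanks. This argues against worms without these windows, as the label says. Reads carried over from the H3K9me3 ChIP of met-2 would also refill the run on V from 1646001, which stayed at 0.021 (0.0056 to 0.053), although 1.29% of equally long stretches were as low. Extra copies of the set-25 region stay open: the 4 kb to the right of the deletion stood 3.59-fold above the genome median relative to the H3K9me3 input of met-2, above 99.995% of equally long stretches, but this is also the longest run named for high values in this library, so its rank decides nothing. The library's own input, at 0.789-fold there, shares the missing run on V with the ChIP, which no other library does, but lacks the set-25 windows, which argues against an origin of both in the same worms alone. An outside sample under this label also stays open and was not tested.

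The difference between arms and middle had opposite signs in the H3K9me3 libraries, -0.19 in met-2 and 0.56 in the library labelled set-25, which was not tested, since each side is 1 library, and with the input of the other mark the signs were no longer opposite (0.12 and 0.72). The value of the library labelled set-25 was 0.46 (0.34 to 0.58) with the H3K9me3 input of met-2, 0.37 (0.31 to 0.43) within deciles of the ratio between the inputs of the 2 marks, and 0.26 (0.05 to 0.46) over windows with H3K9me2 of set-25 at or below its median. As the whole cause, each explanation predicted a value below 0.28, and the first 2 intervals lie above it, though each took away part. This argues against the composition of the inputs as the whole cause. The swap cannot decide on an input of another genotype, since the met-2 input correlated at 0.96 with the input it replaced. It also held the run on V from 1646001, at a ratio of 1.77, where the ChIP stood at 0.021. Reading the intervals against this limit was chosen after the results were seen, and neither lay wholly above 0.42, the stricter limit set beforehand, with the decile value itself below it. H3K9me2-rich windows cannot be told apart from a strain difference, since the third interval spans 0.28, and the strain difference remains untested.

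H3K9me2 of met-2 was higher inside windows enriched for H3K9me3 in met-2, by 0.66 on average. Inputs of the 2 marks differed in composition (the log2 ratio between them had an SD of 1.05 over windows in met-2), but within deciles of that ratio the difference remained 0.47 (0.45 to 0.49), which argues against this as the whole cause. Over all kept windows, without deciles, the Spearman correlation of both marks in met-2 was 0.096. Enrichment in met-2 correlated with the input ratio at 0.68 for H3K9me2 and -0.13 for H3K9me3. No correlation within deciles over all windows was computed, so 0.096 is no baseline for the next value. Inside the H3K9me3-enriched windows and within deciles, the correlation of both marks averaged 0.475 across windows, which are not independent replicates. This value is consistent with an H3K9me2 antibody that also binds H3K9me3, and as much with H3K9me2 made at these sites without MET-2, and no value here separates the 2.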

How the results depend on the processing

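No paired analysis was possible because the columns carry 1 value per group, and the only column name that ends in a number (1, H3K9me3 ChIP of met-2) has no partner. Replicate block, leave-one-out, 2-group fits, eBayes options, gene, gene list and repeat alternatives were not run for the same reason or for lack of a genome of the build. Of the values recomputed, 49 stayed within 1.5 times (enriched shares, and comparisons by the total of both directions) or within counting error (arm values), 60 moved and 13 turned direction. The shares per direction moved further in some of the 49. Alternatives on inputs, floor and totals were chosen after seeing the data. The cause was not tested unless named. Shares are percent of windows, "met-2/set-25" and "H3K9me2/H3K9me3" name strain and mark comparisons, and arm values (arms minus middle) are listed for H3K9me2 in met-2 and set-25, then H3K9me3 in met-2 and labelled set-25 unless named. Centring each library gave differences of 33.5 for met-2/set-25 in H3K9me2 (10.05 higher, 23.5 lower), 14.5 (5.32, 9.16) and 53.97 (38.7, 15.2) for H3K9me2/H3K9me3 in met-2 and set-25, and 58.3 (16.9, 41.4) for the interaction, all 4 in the opposite direction. Enriched shares became 23.8 (H3K9me2 set-25), 6.32 (H3K9me3 met-2) and 13.8 (labelled set-25), because centring moves the threshold. Quantile normalisation gave 37.4 for met-2/set-25 in H3K9me2 (18.9, 18.4), and 40.6 (19.9, 20.6) and 37.5 (18.8, 18.6) for H3K9me2/H3K9me3 in met-2 and set-25, both turned. Giving all libraries the same distribution favours near-equal shares, so both turns, counted among the 13, show no direction. Enriched shares were 6.30 in every library by construction, and arm values -0.16, 0.99, -0.28 and 0.40. Over windows with mean enrichment above 0, met-2/set-25 turned in H3K9me2 (57.8: 18.6, 39.2) and H3K9me3 (50.996: 14.7, 36.3), as did H3K9me2/H3K9me3 in set-25 (57.9: 36.2, 21.8) and the interaction (58.1: 26.5, 31.6), and in met-2 it was 30.6. This filter used the compared values themselves, so its turns decide no direction. Windows of 5 kb gave 31.6 for met-2/set-25 in H3K9me3 (27.3, 4.33) and 4.26 and 38.7 for H3K9me2/H3K9me3 in met-2 and set-25. With a pseudocount of 1 CPM, H3K9me2/H3K9me3 in met-2 was 11.2, with 12.6 higher and 32.3 lower in set-25 and 39.5 and 11.997 in the interaction, enriched shares 0.428 (H3K9me2 met-2) and 4.51 (labelled set-25), and arm values -0.066, 1.17, -0.17 and 0.39. A threshold of 0.5 enriched 11.8 (H3K9me2 met-2), 8.03 (H3K9me3 met-2) and 20.5 (labelled set-25). At 2 the 4 libraries had 0.00366, 4.81, 1.46 and 0.266. Arms of 33.3% gave arm values of -0.057, 1.25 and 0.63 (not H3K9me3 met-2), and medians -0.041, 1.23, -0.12 and 0.54. With the input of the other strain, the H3K9me2 met-2 enriched share was 0.284 and arm values were -0.12, 1.499, -0.086 and 0.46. With the input of the other mark, H3K9me2/H3K9me3 in met-2 was 66.1, enriched shares 9.30 (H3K9me2 met-2), 10.2 (H3K9me3 met-2) and 17.1 (labelled set-25), and arm values -0.38, 1.29, 0.12 (turned) and 0.72. Without input, H3K9me2/H3K9me3 in met-2 was 34.8 and arm values -0.37, 1.21, -0.17 and 0.48. Totals without the most covered windows turned H3K9me2/H3K9me3 in set-25 (56.0: 33.4, 22.6) and the interaction (59.9: 25.7, 34.1), and gave 30.9 higher and 16.1 lower for met-2/set-25 in H3K9me2 and 7.48 and 7.42 for H3K9me2/H3K9me3 in met-2. The H3K9me2 set-25 enriched share was 17.4, and arm values were 1.48, -0.19 and 0.58 (not H3K9me2 met-2). Without a floor, arm values were 1.45, -0.18 and 0.56 (not H3K9me2 met-2). The arm excess of H3K9me2 in set-25 lay between 0.99 and 1.499 under every alternative run. Depth limits single windows most in the H3K9me2 ChIP of set-25, where the Poisson interval at the median window spanned 30.6% to either side. The H3K9me3 ChIP labelled set-25 had 16520 empty windows at a similar total, and the cause was not tested.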

Other observations

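Part of the windows over-covered in the inputs carried H3K9me2 in set-25. This group of windows was chosen after the data were examined: 30 windows in 12 runs where each of the 4 inputs held at least 3 times its median. H3K9me2 of set-25 had a median log2 enrichment of 2.76 there and exceeded 1 in 19 of 30 windows (63.3%, against 10.3% of all windows). By run, 6 of 12 exceeded 1 and 3 lay below 0, down to -0.80. The longest run held 10 of the 19 windows, and the other 20 windows had a median of 0.78 with 9 above 1. H3K9me2 of met-2 had a median of 0.49 with 0 windows above 1, H3K9me3 of met-2 -0.76 with 0, and the library labelled set-25 0.23 with 3. The longest of these runs lay near the right end of I, from 15063501 to 15068500, where the WBcel235 gene order ends in the ribosomal RNA genes rrn-1.1, rrn-2.1, rrn-3.1 and rrn-1.2. The match is by order, not by position. H3K9me2 stood there at 4.17 in set-25 (4.16 to 4.17), 17.96-fold over input, and at 0.47 in met-2. This run took 7.12% of the counts of the H3K9me2 ChIP of set-25 and 0.293% of that of met-2. Its inputs differed too, at 302 and 354 times the median window for H3K9me3 (labelled set-25 and met-2) and 73.9 and 38.8 for H3K9me2. The run took 0.396% and 0.211% of the H3K9me2 inputs (set-25 and met-2) but 1.39% and 1.51% of the H3K9me3 inputs. Over the H3K9me3 inputs, the set-25 value would thus be smaller and the met-2 value below 0. The interval above does not cover this dependence on the input. Further runs with H3K9me2 in set-25 were X from 7077501 to 7078500 (4.98, against 0.55 in met-2), I from 3171501 to 3172000 (3.56 against 0.45), V from 5284001 to 5285500 (2.80 against 0.85), IV from 13549001 to 13549500 (1.85 against -0.29) and I from 933501 to 934000 (1.22 against 0.51). The 5 windows on III from 13779001 to 13781500, covered 6.47 to 6.97 times the median in the inputs, showed no such enrichment (0.03 in set-25, 0.08 in met-2).

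Windows enriched for H3K9me3 in met-2 and for H3K9me2 in set-25 coincided in 1005 cases, 12.8% of the former, against 803 for independent placement and 569 within chromosome parts. Of the 214 H3K9me3 domains of met-2, 31 exceeded 1 for H3K9me2 in set-25, and 26 of these were among the 50 on arms, 2 among the 138 in middle parts and 3 among the 26 on X. The 5 with the highest H3K9me2, picked after their values were seen, were on V from 18443501 to 18455500 (H3K9me2 of set-25 4.25, H3K9me3 of met-2 2.09), X from 1766001 to 1775000 (4.13 and 2.21), V from 19270001 to 19282000 (4.09 and 2.11), III from 2667001 to 2675000 (3.70 and 1.79) and V from 17133501 to 17145000 (3.28 and 3.57). Over all 214 domains H3K9me2 of set-25 had a median of -1.01, against -1.33 over all windows. The domain values came from summed counts and 138 of the domains lay in middle parts, so -1.33 is not a matched background. The highest H3K9me3 domain of met-2 lay in the middle of V, from 8477001 to 8486500, at 3.83 (3.81 to 3.86), with H3K9me2 of set-25 at 0.09.

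Chromosome IV stood out by its right arm, the part with the lowest share of enriched windows for H3K9me2 in both strains among the arms, 8.29% in set-25 and 0.44% in met-2, and for H3K9me3 in met-2, 0.59%. Of the piRNA genes of WBcel235, 95.8% lie on IV. Whether they fall in this part was not examined, so no link to the low shares is drawn.

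Inputs were more alike within a mark than within a strain. Across windows the Spearman correlation of counts was 0.96 between the H3K9me3 inputs and 0.72 between the H3K9me2 inputs, but 0.10 between the inputs of the 2 marks labelled set-25 and -0.27 between those of met-2.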
